A study of Homo sapiens with 4 samples.

How the data were processed

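Libraries from the H1944 lung cancer cell line were compared in 2 groups, DMSO and BAY1217389, with 2 biological replicates in each. Cells were exposed for 48 h and RNA was collected 24 h after the medium was changed, per the labels' protocols. RNA was extracted with an RNeasy kit, quantified with RiboGreen and made into libraries with the Illumina TruSeq Stranded mRNA kit, which selects poly(A) RNA and marks strand, per the labels' protocols. The genome build named in the submitters' processing notes is hg18, but the count sheets also hold RefSeq identifiers that were issued after that build, so the annotation behind the counts is uncertain. The aligner, the counting tool and whether counting used strand are not given in the sources used here, so reads of overlapping, antisense, read-through and near-identical genes are treated as uncertain.

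The authors deposited whole-number read counts per gene, with gene symbols and RefSeq identifiers per the file headers. Each of the 4 workbooks held a count sheet of 46427 rows. Of these, 21455 had 0 reads in every library, 0 named no gene, and 1 symbol stood on 3 rows, which were kept apart. The workbooks also held 4 further columns of per-sample values, 16 with repeats, whose names match no sample of the series, and they were not used here. Total counts were 39332931 and 38904473 in the DMSO libraries and 43661342 and 43067647 in the BAY1217389 libraries. A count of 0 allows up to 3 reads, that is 0.0762 and 0.0767 CPM in the DMSO libraries, 0.0689 and 0.0701 CPM in the BAY1217389 libraries and 0.0382 CPM over both DMSO libraries. Reads without molecular identifiers are not independent molecules, so these limits and the 95% binomial intervals of count ratios cover counting error only.

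Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left out 29689 rows and kept 16738 genes. TMM factors lay between 0.994 and 1.01. A quasi-likelihood model with treatment as its term and robust dispersions was tested two-sided with glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The fit had 2 residual degrees of freedom per gene and borrowed 31.1 prior degrees of freedom from all genes, with a common biological coefficient of variation of 3.99%. CPM are counts divided by library size times TMM factor. Fold changes are log2, BAY1217389 minus DMSO, and standard errors come from the fitted model. Genes with 0 reads in both DMSO libraries have a fitted fold change that depends on the prior count, so their fold is given as a lower bound against 3 reads over that group. Their replacement by these bounds left every list median as it was.

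Lists of genes were tested with camera from limma 3.58.1 on log-CPM with prior count 2 and a preset inter-gene correlation of 0.01, adjusted over the 26 lists. The lists hold 650 genes, of which 602 were tested, and they were written from textbook knowledge before the data were examined, as were the groups, the tests, the rule for named genes and most alternatives. Camera called 11 lists higher and 8 lower. With an estimated correlation, 0 lists passed, 11 had unadjusted p under 0.05 and the smallest adjusted p was 0.0995, a version limited by the 2 residual degrees of freedom. Estimated correlations ran from -0.07 for interferon genes and receptors to 0.38 for mitochondrially encoded transcripts, with 0.17 for MHC class I. Where they exceed the preset 0.01, the camera p-values with the preset may be too small, though these estimates are themselves uncertain. The fry test, which asks whether the genes of a list move on balance one way and does not compare them with other genes, passed for 25 lists, and its mixed version, for change in either direction, for 26. In 0 lists did the median, the mean and the test differ in sign. A few genes stand in more than 1 list.

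The genes named were the 10 largest rises and 10 largest falls among genes past the threshold that reached 5 CPM in the higher group and had both libraries of one group above both of the other, leaving out uncharacterised loci, noncoding and antisense symbols and open reading frames. To these were added the up to 4 members of each list with the smallest p-values, and 10 genes whatever their values (TTK, CGAS, STING1, TBK1, IRF3, TREX1, IFNB1, CXCL10, CDKN1A and MKI67). Some genes that this rule names are not reported here.

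The libraries of a group differed by more than sampling noise. A chi-square comparison of their counts gave 3.74 per degree of freedom over 16168 genes with at least 20 reads for DMSO and 3.93 over 16849 genes for BAY1217389, so neither pair looked like repeat deposits of a single library. Counting each library as a biological replicate rests on the labels alone. Across genes, which are not independent replicates, Pearson correlations of log-CPM were 0.989 and 0.992 within groups and 0.979 to 0.980 between groups. Reads of cytosolic ribosomal RNA made up 1.87 and 1.58% of the DMSO libraries and 1.81 and 1.99% of the BAY1217389 libraries. The 10 most abundant genes took 7.79, 7.65, 7.32 and 7.47% of reads in the same order. The labels name no sequencing batch.

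Counts were simulated for the 16738 genes of this comparison, with the DMSO means and the library sizes of the real samples. The test was run on them with 50 genes changed at each fold. It recovered 38% of genes changed 1.2-fold, 64% at 1.5-fold, 90% at 2-fold and 90% at 4-fold, with 5 false calls. It called the list that had been moved and 0 of 100 lists that had not. Simulated genes were drawn independently of each other, so this does not check the preset inter-gene correlation. Changed genes were few and balanced between rises and falls, and dispersions followed the fitted trend. The simulation therefore does not check normalization with many unbalanced changes, or scatter of dispersion between genes.

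Alternatives were a term for replicate number, leaving out each library in turn, median-of-ratios size factors, library totals alone, DESeq2 1.42.0, no low-count filter, a stricter filter of at least 5 CPM in 2 libraries, limma-voom, an adjusted p threshold of 0.01, a test against a fold of 1.2 with glmTreat, and camera with estimated correlation or on ranks. Thinning every library to the smallest total was added after the data were seen. With DESeq2, lists were tested by the pre-ranked form of camera on its Wald statistics, so those list p-values come from that form. Gene neighbours came from GENCODE 29 and RefSeq on GRCh38, used for the order of genes and the gap between them. No coordinates are printed since the build and annotation of the counts are uncertain. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.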

Results

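RNA from H1944, a human lung cancer cell line, was sequenced after exposure to BAY1217389 or to its vehicle DMSO. BAY1217389 inhibits the kinase MPS1, also called TTK, which holds dividing cells in mitosis until every chromosome is attached to the spindle. Cells were kept in inhibitor or vehicle for 48 h and harvested 24 h after its removal. Each treatment had 2 biological replicates, 4 libraries in all, and the stated purpose of the series concerns negative regulators of the STING pathway, which signals the presence of DNA in the cytosol. The DMSO libraries held 39332931 and 38904473 reads assigned to genes and the BAY1217389 libraries 43661342 and 43067647. Reads fell on 20563 and 20447 genes in the DMSO libraries and on 21742 and 21773 genes in the BAY1217389 libraries. The BAY1217389 libraries were deeper, but after thinning to equal depth the counts were still 20553 and 20447 against 21639 and 21678. Levels are given as CPM, the reads of a gene scaled to library size, as the mean ± SD over the 2 libraries of a group. An SD from 2 libraries can lie below counting error, so a small SD is not a measure of precision. At the depth before thinning, a count of 0 in both DMSO libraries allows up to 0.0382 CPM, a limit that covers counting error only.

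BAY1217389 changed the expression of many genes, and the larger changes were mostly increases. Of 16738 genes, 2428 were higher after BAY1217389 and 2232 were lower, together 27.8%. By at least 1 on the log2 scale, 537 genes were higher and 40 were lower. The 10 largest rises among genes reaching 5 CPM were the type III interferon genes IFNL2, IFNL1 and IFNL3, the antiviral genes MX2, CMPK2, RSAD2 and RTP4, the lysosomal peptide transporter SLC15A3, the actin-binding protein gene NEXN and the galectin gene LGALS9. MX2 went from 0.853 ± 0.058 to 106 ± 6.14 CPM, a log2 fold change of 6.96 (SE 0.18). CMPK2 rose from 2.53 to 91.1 CPM, RSAD2 from 2.88 to 81.1 CPM, RTP4 from 0.242 to 6.61 CPM, SLC15A3 from 0.14 to 7.84 CPM, NEXN from 0.267 to 10.1 CPM and LGALS9 from 0.65 to 12.8 CPM. The 10 largest falls were smaller except for COMMD3-BMI1, which went from 9.60 to 0.382 CPM, a log2 fold change of -4.64 (SE 0.26). COMMD3-BMI1 and MSH5-SAPCD1 (-1.18) are read-through genes that share sequence with their neighbours, so their counts are uncertain, and the summed counts of COMMD3-BMI1, COMMD3 and BMI1 had a log2 fold change of -0.01. ACO1, the cytosolic aconitase that also acts as an iron regulatory protein, fell from 114 ± 0.0736 to 42.0 ± 0.235 CPM (log2 fold change -1.45, SE 0.04). The others were the transcription factor genes AKNA (-1.08) and MXD3 (-1.05) and 5 genes active in dividing cells, PRR11 (-1.20), PLK1 (-1.05), CCNB2 (-1.05), DEPDC1 (-1.03) and KIF20A (-1.02). Calls rest on edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. Tested against a fold change of 1.2, 891 genes were higher and 303 lower. Among genes with at least 5 CPM in 2 libraries, 198 were higher and 10 lower by at least 1 on the log2 scale, and DESeq2 called 23 lower by that much.

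**Figure D1:**
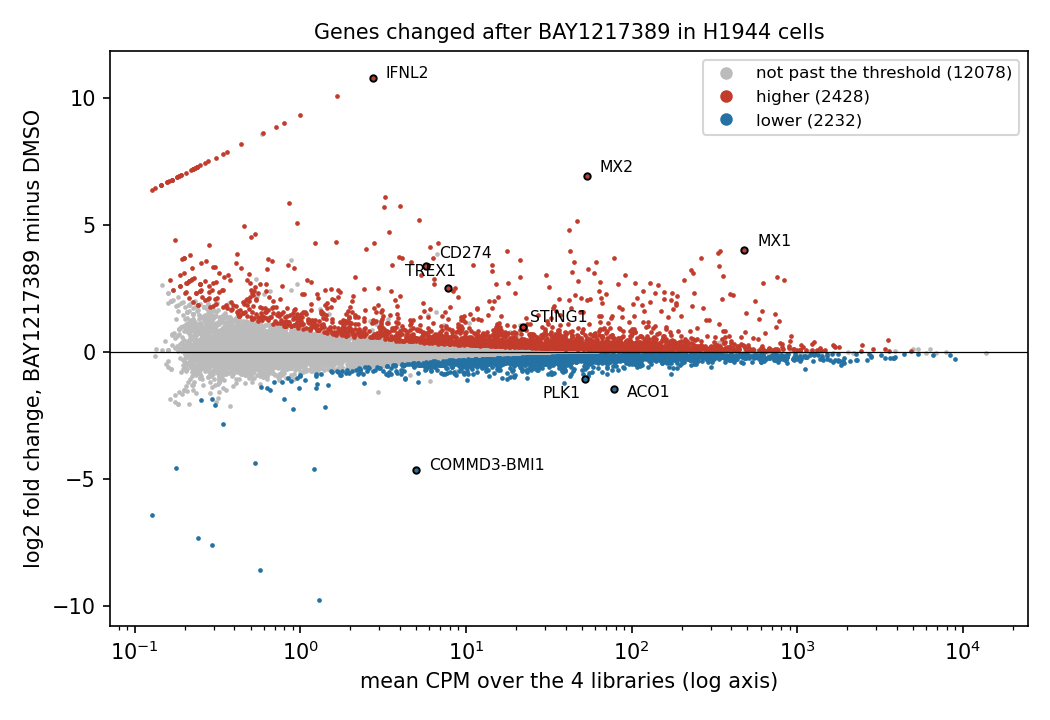
Log2 fold change of each tested gene, BAY1217389 minus DMSO, against its mean CPM over the 4 libraries on a log axis; 2428 genes were higher (red), 2232 lower (blue) and 12078 did not pass the threshold (grey), with 9 genes circled, of which CD274 was chosen after its values were seen. Points on the straight line at upper left are genes with 0 reads in both DMSO libraries, and the 5 lowest points at lower left are genes with 0 reads in both BAY1217389 libraries, whose fitted fold changes depend on the prior count.

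Interferon genes and interferon-stimulated genes rose together. Every one of the 58 tested interferon-stimulated genes was higher after BAY1217389, 56 of them by at least 1 on the log2 scale, with a median log2 fold change of 2.75 (6.73-fold). MX1, a GTPase that blocks viruses, went from 55.3 ± 1.12 to 902 ± 0.973 CPM, a log2 fold change of 4.03 (SE 0.03). IFIT1, which binds foreign RNA, rose from 40.6 to 645 CPM, OAS2, an RNA-activated synthetase, from 41.4 to 624 CPM, and IFI6 from 170 to 1333 CPM. Transcripts of the interferons themselves were nearly absent from DMSO cells. IFNB1, the interferon beta gene, had 0 reads in both DMSO libraries and 26 and 22 in the BAY1217389 libraries, at least 14.5-fold higher than the limit set by 3 reads over the DMSO group (edgeR adjusted p = 2.55e-05). CXCL10, an interferon-induced chemokine gene, had 0 reads in both DMSO libraries and 72 and 66 after BAY1217389, at least 41.8-fold higher than that limit (edgeR adjusted p = 4.15e-10). IFNL1 went from 5 and 2 reads to 241 and 309. IFNL2 went from 0 in both DMSO libraries to 202 and 270, at least 143-fold higher than that limit, and IFNL3 from 0 and 9 to 239 and 302, but these genes are near-identical copies whose reads cannot be firmly told apart. Lower 95% binomial limits of the ratio between groups, which also take in the counting error after BAY1217389, were 11.4 for IFNB1, 33.6 for CXCL10 and 116 for IFNL2. Of 10 tested interferon and receptor genes, 9 were higher, with a median log2 fold change of 0.47, and the receptor gene IFNGR1 rose by 0.21. That median was 0.73 without DMSO replicate 1, 0.84 without BAY1217389 replicate 1 and 0.22 with the stricter filter. Counts adjusted over the list alone were also 58 and 9. Against all other genes, camera gave adjusted p = 2.2e-52 for the interferon-stimulated genes and 5.17e-06 for the interferons and receptors. With an estimated correlation the adjusted p was 0.0995 for both lists, and this version of camera rests on 2 residual degrees of freedom.

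Of 16 tested components of the cGAS-STING pathway, 8 were higher, 1 was lower (SLC19A1, named after its values were seen) and 7 did not pass, with a median log2 fold change of 0.15. STING1, the adaptor itself, went from 14.6 ± 0.62 to 29.5 ± 1.04 CPM (log2 fold change 1.01, SE 0.08). IFI16, a nuclear DNA sensor, rose from 101 to 362 CPM, IRF7, an interferon regulatory factor that is also among the interferon-stimulated genes listed, from 23.8 to 117 CPM, and the kinase gene IKBKE from 5.95 to 10.4 CPM. CGAS, the cytosolic DNA sensor, had a log2 fold change of 0.28 (SE 0.08, edgeR adjusted p = 0.0107). The CGAS call was lost without DMSO replicate 1 (edgeR adjusted p = 0.142) and without BAY1217389 replicate 1 (0.187), within a range of 0.00208 to 0.187 over all alternatives. TBK1, the kinase downstream of STING, had a log2 fold change of 0.11 (edgeR adjusted p = 0.0719), and it passed with libraries thinned to equal depth (0.0421), an alternative added after seeing the data, and with the stricter filter (0.0239), within a range of 0.0239 to 0.399. IRF3, the transcription factor TBK1 activates, had a log2 fold change of 0.07 (edgeR adjusted p = 0.391), and the sign turned without BAY1217389 replicate 2 (-0.0157). When adjusted over the list alone, 9 components were higher and 1 lower. Camera gave the list adjusted p = 0.00153, and adjusted p = 0.138 with an estimated correlation.

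Genes listed as negative regulators of STING signalling, the subject of the series, moved in both directions. The list was written by hand, and whether each member restrains STING in these cells was not tested. Of 24 tested, 8 were higher, 5 were lower and 11 did not pass, with a median log2 fold change of 0.04. TREX1, the exonuclease that degrades cytosolic DNA, went from 93 and 86 reads to 633 and 523, a log2 fold change of 2.55 (SE 0.15, edgeR adjusted p = 6.74e-17). SAMHD1, a nucleotide hydrolase, rose from 12.2 to 106 CPM, ADAR, an RNA-editing enzyme, from 494 to 988 CPM, and TRIM38, a ubiquitin ligase, from 19.9 to 66.5 CPM. USP18, which restrains interferon receptor signalling and is itself among the interferon-stimulated genes listed, rose from 11.1 to 145 CPM, with reads that may be shared with related copies such as USP41. The 5 lower genes, chosen after their values were seen, were APEX1 (-0.37), USP21 (-0.25), NLRX1 (-0.24), PCBP2 (-0.24) and RNASEH2B (-0.21). With p adjusted over the list alone, 10 were higher and 6 lower. Camera did not call the list (adjusted p = 0.159, and 0.307 with an estimated correlation), whereas it passed on limma-voom values (0.0336). Pre-ranked camera on DESeq2 Wald statistics gave the list adjusted p = 2.4e-11, and the range over all alternatives was 2.4e-11 to 0.422. Its median lay between -0.02 and 0.06 over the alternatives.

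**Figure D2:**
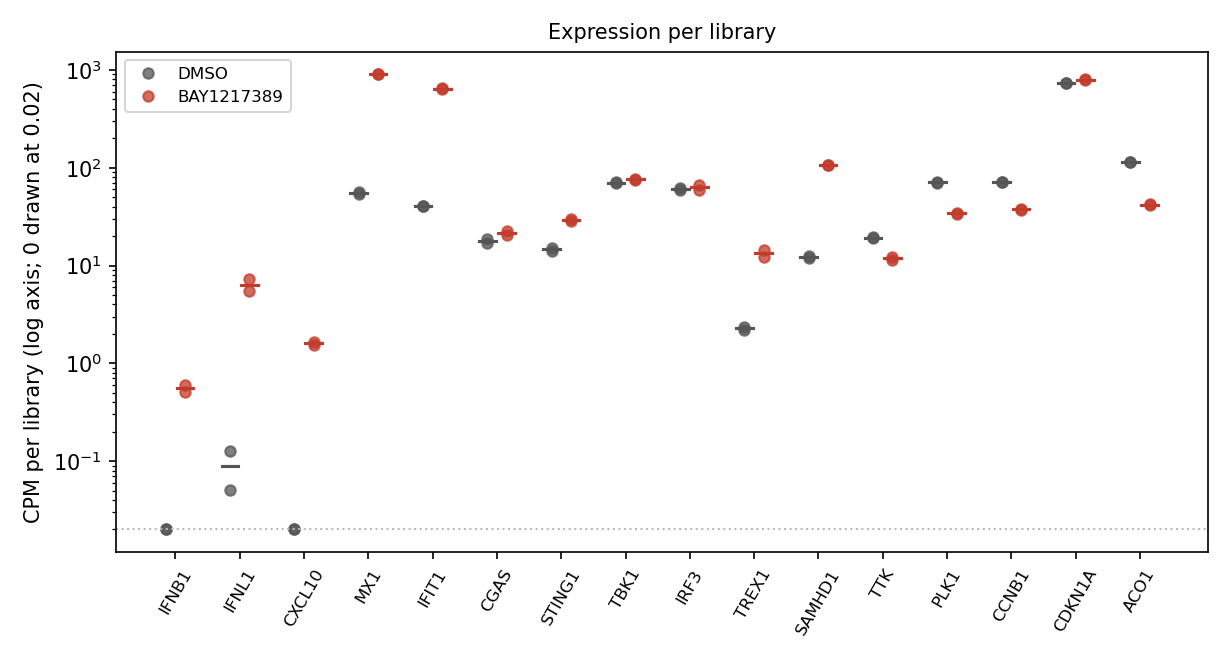
CPM of 16 genes in each library, on a log axis, with dots for the 2 DMSO (grey) and 2 BAY1217389 (red) libraries, lines for group means and 0 drawn at 0.02. IFNB1 and CXCL10 had 0 reads in both DMSO libraries, MX1 lay at 55.3 against 902 CPM, and the ranges of PLK1 and ACO1 did not overlap between groups.

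Inflammatory and antigen presentation genes were also higher. Of 26 tested NF-kB and inflammatory cytokine genes, 25 rose, with a median log2 fold change of 0.92. The cytokine gene IL6 went from 5.45 ± 0.19 to 22.1 ± 1.03 CPM (log2 fold change 2.02, SE 0.10), the apoptosis inhibitor BIRC3 from 48.0 to 126 CPM, the chemokine CXCL5 from 257 to 453 CPM and the mitochondrial superoxide dismutase SOD2 from 481 to 804 CPM. All 19 genes of MHC class I antigen presentation rose, with a median log2 fold change of 1.41. The peptide transporter TAP1 went from 67.1 to 309 CPM, the light chain B2M from 382 to 1092 CPM, and the heavy chains HLA-B from 52.4 to 206 CPM and HLA-C from 463 to 1077 CPM, where reads can be shared between HLA genes. The counts adjusted over the list alone were again 25 and 19. Camera gave adjusted p = 1.49e-14 for the inflammatory list and 3.96e-17 for MHC class I, and adjusted p = 0.0995 for each with an estimated correlation.

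Genes of mitosis fell. TTK, which encodes the inhibited kinase, went from 19.4 and 19.2 CPM to 12.1 and 11.5 CPM, a log2 fold change of -0.71 (SE 0.09, edgeR adjusted p = 8.24e-08). Among 30 spindle checkpoint and kinetochore genes, 27 fell and 3 did not pass, with a median log2 fold change of -0.59. PLK1, a mitotic kinase, went from 70.7 ± 0.912 to 34.1 ± 0.946 CPM, AURKA from 83.8 to 48.5 CPM, CDC20, an activator of the anaphase-promoting complex, fell by 0.95 and the kinetochore gene CENPF by 0.76 on the log2 scale. Among 30 G2/M genes, 29 fell, with a median of -0.68. They included TOP2A, which untangles DNA (222 to 124 CPM), the cyclin CCNB1 (71.8 to 37.8 CPM), TPX2 (log2 fold change -0.61) and FOXM1, a transcription factor for mitotic genes (-0.58). Falls were smaller among 37 DNA replication genes, of which 18 fell and 19 did not pass (median -0.16). TK1 (-0.40), TYMS (-0.35) and RRM1 (-0.34), all enzymes of nucleotide synthesis, were lower. The proliferation marker MKI67 had a log2 fold change of -0.47 (edgeR adjusted p = 6.21e-10). Adjusted over the list alone, 28 checkpoint and 29 G2/M genes were lower, and 19 replication genes were lower with 1 higher. Camera gave adjusted p = 4.42e-16, 7.91e-19 and 5.17e-06 for these 3 lists, and adjusted p = 0.0995 for each with an estimated correlation.

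Replication-dependent histone genes rose while p53 targets and DNA repair genes were mixed. Of 14 tested histone genes, 10 were higher (median log2 fold change 0.50), among them H2AC19 (0.78), H4C15 (0.74), H2AC6 (0.54) and H2BC12 (0.39). Histone genes are close copies of each other and most of their transcripts lack a poly(A) tail, so poly(A)-selected counts of them are uncertain. Of 32 p53 targets, 12 were higher, 6 were lower and 14 did not pass, with a median of 0.09. PMAIP1, which encodes the pro-apoptotic protein NOXA, went from 108 to 215 CPM. PLK2 (0.56), FAS, a death receptor (0.45), and GDF15, a stress cytokine (0.23), were higher. CDKN1A, the p53-induced cell cycle inhibitor p21, had a log2 fold change of 0.11 (SE 0.02, edgeR adjusted p = 8.36e-04). Of 25 DNA repair genes, 10 were lower, 2 were higher and 13 did not pass (median -0.18), with FANCD2 (-0.46), BRCA1 (-0.35), FANCI (-0.25) and RPA1 (-0.21) lower. Adjusted over the list alone, 10 histone genes were higher, 12 p53 targets were higher and 7 lower, and 3 repair genes were higher and 12 lower. Camera gave adjusted p = 5.17e-06 for histones, 0.00499 for repair and 0.124 for p53 targets, and adjusted p = 0.0995, 0.307 and 0.282 with an estimated correlation. On DESeq2 values the repair call was lost (0.0561, range 0.00121 to 0.307) and the p53 list passed (0.0379), as it did with limma-voom (0.0362, range 0.0362 to 0.391).

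**Figure D3:**
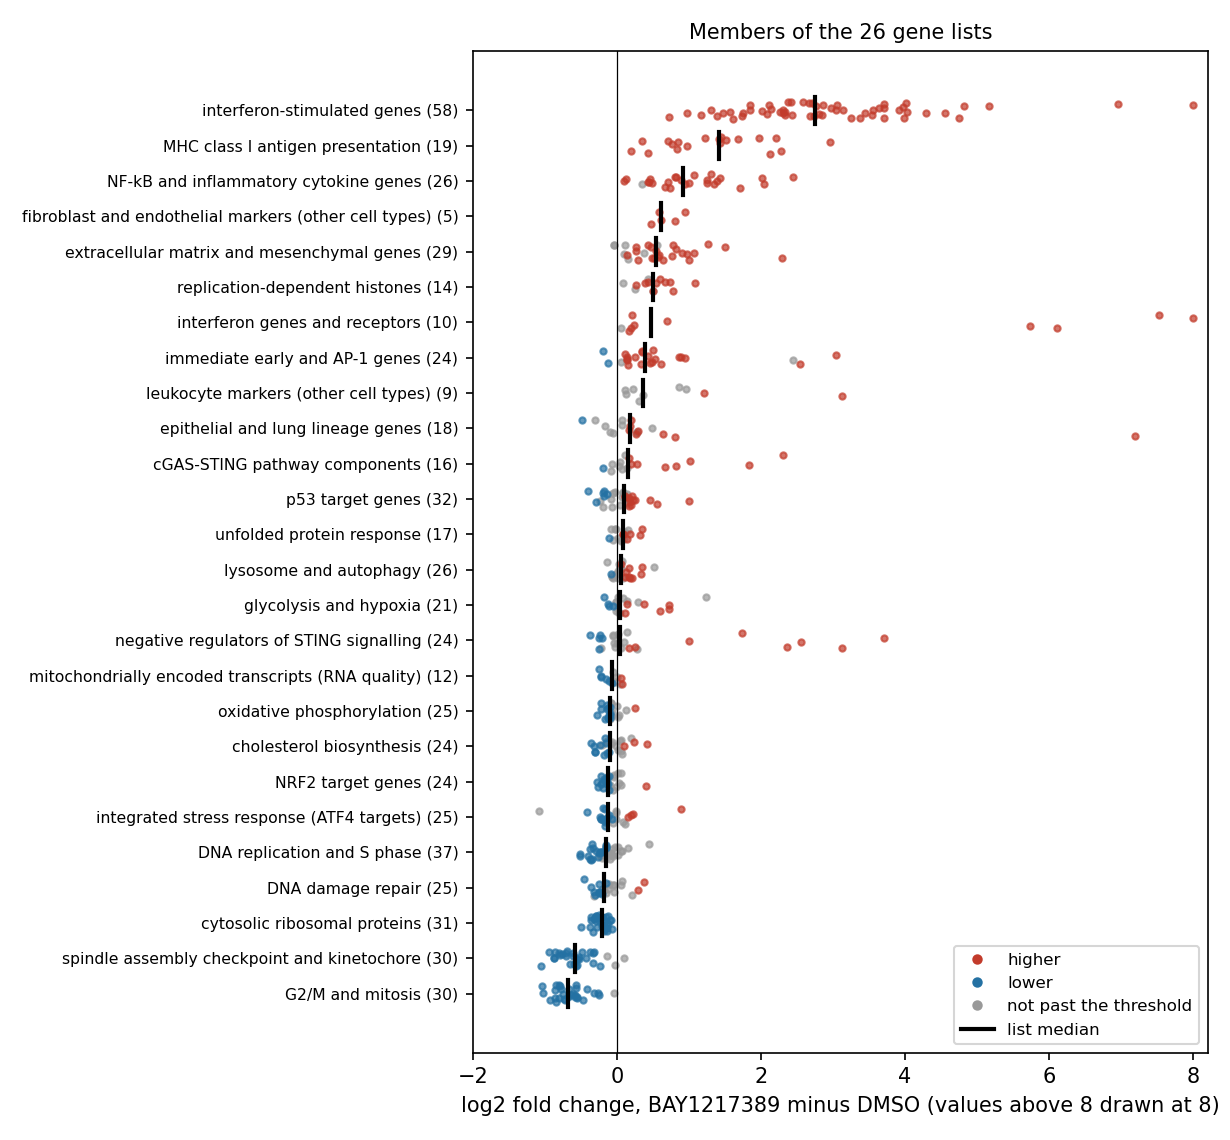
Log2 fold change, BAY1217389 minus DMSO, of each tested member of the 26 gene lists, with red for higher, blue for lower and grey for not past the threshold, a bar at each list's median and values above 8 drawn at 8. Medians run from -0.68 for G2/M genes to 2.75 for interferon-stimulated genes.

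Cytosolic ribosomal protein genes fell by varying amounts. All 31 were lower, with log2 fold changes between -0.49 and -0.07 and a median of -0.21, and RPL3 went from 2141 ± 3.91 to 1521 ± 21.2 CPM. RPS6 (-0.37), RPS2 (-0.36) and RPL4 (-0.33) were lower as well, with reads that processed pseudogenes can share. Of 25 oxidative phosphorylation genes, 14 were lower and 1, NDUFA9 (0.25), was higher, with a median of -0.10. COX5A (-0.28), CYC1 (-0.23) and SDHA (-0.16) were lower. Of 12 mitochondrially encoded transcripts, 6 were lower, 2 were higher and 4 did not pass (median -0.07), with ATP8 (-0.24), ATP6 (-0.22), COX3 (-0.22) and CYTB (-0.15) lower. These transcripts held 5.16 and 5.13% of reads in the DMSO libraries and 4.95 and 4.90% after BAY1217389. By p adjusted over the list alone, 31 ribosomal genes were lower, 17 oxidative phosphorylation genes were lower and 2 higher, and 7 mitochondrial transcripts were lower and 3 higher. Camera gave adjusted p = 8.59e-12, 0.00170 and 0.0697 for the 3 lists, and adjusted p = 0.0995, 0.179 and 0.485 with an estimated correlation. The mitochondrial list passed without the low-count filter (camera adjusted p = 0.0399), with DESeq2 (0.00310) and with limma-voom (0.00193), within a range of 0.00193 to 0.485.

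Stress and metabolic gene lists had medians close to 0, with members moving both ways. Of 25 ATF4 targets of the integrated stress response, 13 were lower and 4 higher (median -0.13): the serine synthesis genes PHGDH (-0.42) and PSAT1 (-0.20) and the cystine transporter gene SLC7A11 (-0.23) fell while ATF3 rose from 25.5 to 47.3 CPM. Of 24 NRF2 targets, 14 were lower and 1, the haem oxygenase gene HMOX1 (0.40), was higher (median -0.12), with TKT (-0.28), AKR1C2 (-0.22) and PGD (-0.21) lower. Of 17 unfolded protein response genes, 6 were higher and 1 lower (median 0.08), with the chaperone genes CALR (0.35), DNAJB9 (0.31), PDIA4 (0.19) and PDIA6 (0.14) higher. Of 24 cholesterol biosynthesis genes, 10 were lower and 3 higher (median -0.10), with FDPS (-0.31) and EBP (-0.31) lower and STARD4 (0.42) and HMGCS1 (0.23) higher. Of 21 glycolysis and hypoxia genes, 6 were higher and 4 lower (median 0.04), among them ADM (0.72), PFKFB4 (0.72), PGAM1 (0.38) and ENO1 (-0.18). Of 26 lysosome and autophagy genes, 9 were higher and 1 lower (median 0.05), with the protease genes CTSL (0.35) and CTSB (0.21), GABARAPL1 (0.33) and NPC1 (0.16) higher. Adjusted over the list alone, the counts higher and lower were 5 and 13 for ATF4 targets, 1 and 16 for NRF2 targets, 6 and 1 for the unfolded protein response, 3 and 12 for cholesterol, 7 and 4 for glycolysis, and 11 and 1 for lysosome genes. Camera called ATF4 targets (adjusted p = 0.0215) and NRF2 targets (0.00153) lower, with adjusted p = 0.179 and 0.138 with an estimated correlation. Camera did not call the unfolded protein response (adjusted p = 0.0915), cholesterol (0.0720), glycolysis (0.124) or lysosome (0.0720) lists, and with an estimated correlation their adjusted p was 0.282, 0.282, 0.504 and 0.316. The ATF4 call was lost without BAY1217389 replicate 1 (camera adjusted p = 0.0516) and with the stricter filter (0.150), within a range of 0.00120 to 0.179. Cholesterol genes passed without DMSO replicate 2 (camera adjusted p = 0.0456), without the low-count filter (0.0356) and with limma-voom (0.0249), within a range of 0.0249 to 0.282. The unfolded protein response passed with the stricter filter (camera adjusted p = 0.0484) and limma-voom (0.0196), within a range of 0.0196 to 0.282, and lysosome genes with DESeq2 (0.0289), the stricter filter (0.0427) and limma-voom (0.00638), within a range of 0.00638 to 0.316.

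Immediate early and extracellular matrix genes rose, and epithelial genes rose in part. Of 24 immediate early and AP-1 genes, 20 were higher and 2 lower (median log2 fold change 0.39). EGR1, a transcription factor induced by growth signals, went from 1.15 ± 0.19 to 9.49 ± 0.66 CPM, JUN from 32.5 to 62.7 CPM and the phosphatase gene DUSP5 from 291 to 444 CPM. Of 29 matrix and mesenchymal genes, 22 were higher and 7 did not pass (median 0.55). PLAUR, a receptor gene, rose from 75.9 to 134 CPM and fibronectin FN1 from 25.2 to 47.0 CPM. Of 18 epithelial and lung lineage genes, 8 were higher and 1 lower (median 0.18), with MUC5AC (0.80), CLDN4 (0.64), KRT8 (0.29) and KRT18 (0.19) higher and HNF4A, named after its values were seen, lower (-0.48). Adjusted over the list alone, 21 immediate early genes were higher and 2 lower, 24 matrix genes were higher, and 9 epithelial genes were higher and 1 lower. Camera gave adjusted p = 4.54e-08, 8.59e-12 and 0.0141 for the 3 lists, and adjusted p = 0.0995, 0.0995 and 0.179 with an estimated correlation. The epithelial call was lost without DMSO replicate 1 (camera adjusted p = 0.0954, range 0.00154 to 0.179), and the epithelial median was 0.10 without BAY1217389 replicate 1.

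Most markers of other cell types were low or too low to test, and some of those tested rose along with the matrix genes. PTPRC, the general leukocyte marker, had 0 reads in all 4 libraries. Of 9 tested leukocyte markers, 2 were higher and 7 did not pass (median log2 fold change 0.36). CD68, a lysosomal protein gene, went from 70.8 ± 1.86 to 163 ± 2.11 CPM and the lysozyme gene LYZ from 0.0639 to 0.581 CPM, while CD74 (0.96) and CD4 (0.85) did not pass. All 5 tested fibroblast and endothelial markers were higher (median 0.61), among them LUM (log2 fold change 0.61), DCN (0.47), COL1A1 (0.59), which also stands in the matrix list, and FAP (0.80). Also adjusted over the list alone, 2 leukocyte and 5 fibroblast and endothelial markers were higher. Camera gave adjusted p = 0.0141 for leukocyte and 6.56e-04 for fibroblast and endothelial markers, and adjusted p = 0.316 and 0.138 with an estimated correlation. The leukocyte call was lost without BAY1217389 replicate 2 (camera adjusted p = 0.127, range 0.00189 to 0.316), with a median of 0.11, and the median was 0.61 without DMSO replicate 1, 0.78 without BAY1217389 replicate 1 and 0.68 with the stricter filter. The fibroblast and endothelial call was lost on DESeq2 values (pre-ranked camera adjusted p = 0.146, range 1.58e-05 to 0.146), where the median was higher at 1.07, as it was without the low-count filter (1.04). Without BAY1217389 replicate 2, edgeR gave adjusted p = 0.185 for LYZ (range 8.25e-05 to 0.185) and 0.0730 for COL1A1 (range 2.80e-04 to 0.0730). LYZ had 0 reads in DMSO replicate 1, so no fold is given without DMSO replicate 2. FAP was lost without DMSO replicate 1 (edgeR adjusted p = 0.0860), without BAY1217389 replicate 1 (0.0660) or 2 (0.128) and with DESeq2 (0.0572), within a range of 0.0169 to 0.128.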

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

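All settings here were planned except thinning to equal depth, which was chosen only after the results were seen. Counts of changed genes kept within 1.5 times of the reported ones under most settings. Against a fold of 1.2, glmTreat called 891 genes higher and 303 lower. With at least 5 CPM in 2 libraries, 198 genes were higher and 10 lower by at least 1 on the log2 scale, where fewer low genes are tested, and DESeq2 called 23 lower by that much (the cause was not tested). With an estimated correlation, camera called 0 lists higher and 0 lower, a version with 2 residual degrees of freedom. Leaving out each library in turn gave 1720 to 2107 genes higher and 1687 to 1719 lower, 392 to 695 higher and 41 to 57 lower by at least 1, 10 to 11 lists higher and 7 to 9 lower, and -0.75 to -0.67 for TTK, with the lone library assumed to vary like the other group. These fits held 69.2 to 72.7% of the reported calls, with 0 in the opposite direction. Of the named gene values under all settings, 1502 kept direction and side of the threshold, 8 lost the call (LYZ, COL1A1, FAP and CGAS), 2 gained it (TBK1) and 1 changed sign, IRF3 without BAY1217389 replicate 2 (-0.0157, within -0.0157 to 0.142 over the libraries left out, the cause was not tested). Of the list values, 324 were the same, 25 lost the call, 19 of them with an estimated correlation, and 15 gained it, among negative regulators, p53, lysosome, unfolded protein response, cholesterol and mitochondrial lists. Over the settings, the median log2 fold change of all genes lay between -0.01 and 0.03. Depth limits genes with 0 reads in both DMSO libraries, such as IFNB1 and IFNL2, to bounds.

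Replicate numbers are shared by both groups, and the labels do not say whether a number marks paired samples. Across genes, deviations of same-numbered libraries from their group means correlated at 0.04. Counting noise in low genes can hide a shared effect, so this value cannot exclude pairing. With a replicate block, 2466 genes were higher and 2326 lower, 517 and 38 by at least 1, and 4591 of 4660 calls were shared. No list or named gene call changed under the block.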

Other observations

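The gene lists and genes in this part, the overlap gap of ACO1 and both tests of the G2/M genes were chosen only after the results were seen, while the neighbour test of ACO1 and the summed counts of COMMD3-BMI1 were planned before their results. Some of the genes counted next also stand in the lists of the report, and no enrichment test was run on these later lists. Of 18 tested ligands of immune checkpoints and natural killer cells, 13 were higher and 1 lower by edgeR. Of the 13, only TNFSF10 had been counted among the interferon-stimulated genes. That list was written by hand and is not complete, so absence from it does not set a gene apart from the interferon response. CD274, which encodes PD-L1, went from 0.993 ± 0.176 to 10.5 ± 0.329 CPM (log2 fold change 3.39, SE 0.19) and TNFSF10, the death ligand TRAIL, from 2.40 to 26.2 CPM. CD47, a signal against phagocytosis, had a log2 fold change of 0.58 and the poliovirus receptor gene PVR -0.17. Of 14 genes of cytosolic RNA sensing, 12 were higher and 1 lower. Of these 12, 8 had already been counted among the interferon-stimulated genes and ADAR among the genes listed as negative regulators. That leaves TLR3, TRIM25 and ZC3HAV1. The RNA sensor genes DDX58, which encodes RIG-I, and IFIH1, which encodes MDA5, went from 47.9 to 422 CPM and from 19.8 to 163 CPM, while MAVS, their shared adaptor, had a log2 fold change of -0.28.

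The following counts are of further genes picked after their values were seen, with no enrichment test. Of 13 genes of pyroptosis, necroptosis and the inflammasome, 7 were higher, with CASP1 going from 3.29 to 14.7 CPM, MLKL at 0.80 and GSDMD at 0.46 on the log2 scale. Of 6 APOBEC3 cytidine deaminase genes, 3 were higher, APOBEC3B (1.17), APOBEC3F (1.80) and APOBEC3G (2.43), with sequence shared between copies. All 4 tested APOL genes were higher, APOL1 from 83.8 to 271 CPM.

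ACO1 fell more than any other single-locus gene among the named falls and lies tail to tail with DDX58, one of the induced genes. Loss of reads where the genes overlap is argued against by a gap of 533 bases between them in RefSeq and 936 in GENCODE. If induced genes lowered the genes they face, the other 32 convergent neighbours within 10 kb of genes that rose by at least 2 on the log2 scale should be lower than expression-matched genes. Their median was 0.02 against -0.01, one-sided permutation p = 0.7701 from 10000 sets, and 0 of 32 fell as far as ACO1, the lowest being TLDC2 at -0.90. Neighbours were taken at up to 10 kb, whereas ACO1 lies 533 or 936 bases from DDX58. Of the 32, 9 were higher and 5 lower, and the higher ones included IFITM3 and IFI16, both in the lists of the report. Genes that rise for other reasons can raise the median and hide a fall, so the test cannot decide the question. Whether induced genes lower those they face therefore stays open. So does an effect of DDX58 transcription on ACO1 at this locus alone, since a test over other loci cannot decide it.

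COMMD3-BMI1 fell 24.9-fold, yet the summed counts of COMMD3-BMI1, COMMD3 and BMI1 were 108 ± 2.13 CPM in DMSO and 107 ± 0.675 CPM in BAY1217389 libraries, a log2 fold change of -0.0104. COMMD3-BMI1 held 9.60 of the 108 CPM in DMSO libraries, so its loss alone would lower the sum by only a small part. A candidate explanation is that reads were assigned differently among the 3 overlapping genes, for which the flat sum is limited evidence. A change in which transcript is made stays open, since the counts do not hold splice junctions.

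The G2/M genes fell by a median of 0.68 on the log2 scale. Reads taken up by the induced genes cannot account for this: the read share of all genes outside those that rose changed by -0.1049 on the log2 scale. The median of 30 G2/M genes lay below that of 37 DNA replication genes by a log2 difference of -0.5183. A lower share of cycling cells with every phase reduced alike stays open, since replication genes that are also transcribed outside S phase would fall less. A smaller share of cells in or near mitosis, or lower transcription of these genes in each cell, may also be the source, and bulk RNA does not separate them.

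Genes next to induced genes in divergent orientation are given as values. The 16 such genes within 10 kb had a median log2 fold change of 0.34 against 0.00 for matched genes, 9 were higher and 1 lower, and the one-sided permutation p for higher was 1e-04, the smallest that 10000 sets can give. This was the lowest of 6 one-sided values over 3 arrangements, of which the planned one was for lower convergent neighbours. The 57 tandem neighbours had a median of 0.04 against 0.01, with 9 higher and 12 lower and a permutation p for higher of 0.195, and for convergent neighbours that p was 0.230. After thinning each library to 38904473 reads, 20553 and 20447 genes had reads in the DMSO libraries and 21639 and 21678 in the BAY1217389 libraries. The groups still differed at equal depth, which argues against depth as the source of the extra genes. Before thinning, reads on olfactory receptor genes numbered 204 and 182 in the DMSO libraries and 301 and 284 in the BAY1217389 libraries. Whether background reads added to the extra genes was not tested.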
